A study of Mus musculus with 12 samples.

How the data were processed

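Chimeric reads of small RNAs joined to target RNAs were obtained from adult C57BL/6 mouse forebrain by Ago cross-linking and immunoprecipitation with ligation of the small RNA to its target. Per the labels, 7 libraries used anti-Ago2 on whole forebrain, 3 used anti-myc to pull down tagged Ago2 from excitatory neurons, and 2 used control IgG. Tagged Ago2 was induced through Camk2a-CreERT2 with 2 mg tamoxifen daily for 5 days, followed by 14 to 21 days before harvest at 10 to 12 weeks of age. The labels carry the same treatment text for every sample, so whether the anti-Ago2 and IgG mice carried the tag is not stated in the sources used here. Tissue was cross-linked with 3 rounds of ultraviolet light and libraries were read with paired 150 base reads, at a depth stated by the protocol as 61 to 138 (in units of 10 to the power 6 reads) per sample. Depth per library was not given sample by sample, so the precision of each share follows from its number of peaks and is given as a Wilson 95% interval.

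The deposited files are 4 peak lists with annotation, 1 per group of libraries: forebrain replicates 1 to 4 (reps 1-4), forebrain replicates 5 to 7 (reps 5-7), excitatory neurons and IgG. Per the calling summaries, the authors called peaks over the pooled libraries of a group on mm10 with miRBase mouse small RNA names, with at least 3 reads and at least 2 libraries per peak, and mm10 is also given in the submitters' processing notes. The peak caller and the aligner are not given in the sources used here. The deposited score of a peak is a whole number computed by the authors, not scaled to library size. Its definition is not stated; its lowest value of 3 equals the minimum-reads setting, and an alternative that sums scores was run on that basis. The deposited annotation gives each peak 1 feature and 1 gene symbol. The calling summaries list library numbers whose meaning is not stated: reps 5-7 and excitatory neurons share 3 numbers, reps 1-4 shares 0 with any other list, and the 2 IgG libraries carry 1 number.

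Shares of peaks per target region, per small RNA, per fixed miRNA list and per fixed gene list were compared between lists with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Small RNAs, regions and target genes were tested when the 2 lists together held at least 10 peaks. These tests compare the lists, not the conditions. They cover counting error only, because reads were amplified without molecular identifiers, libraries were pooled before calling and each list is a single pooled observation. Peaks of different small RNAs at 1 place are counted separately, which the tests treat as independent. A count of 0 is given with the share that 3 peaks would make.

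Peaks of 2 lists were taken as shared when they had the same small RNA name and overlapped by at least 1 base on the same strand. Small RNA names were shuffled among the peaks of the first list 1000 times for comparison. Members of 10 fixed gene lists (202 genes) with an excitatory peak were compared with 10000 random gene lists matched on 10 groups of reps 1-4 peak number. The gene lists were markers of excitatory neurons, inhibitory neurons, astrocytes, the oligodendrocyte lineage, microglia and vascular cells, and presynaptic, postsynaptic and glutamate receptor, miRNA pathway and activity-regulated genes. The 6 miRNA lists (73 names) were those assigned as enriched in neurons, the oligodendrocyte lineage, astrocytes, microglia and blood cells and vascular cells, and the let-7 family. Whether each member marks its cell type was not tested. Presence of 59 known miRNA and target pairs was counted by annotated gene symbol. These lists, the comparisons of the excitatory and reps 5-7 lists with reps 1-4, their tests and most alternatives were fixed before the data were examined.

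Chosen after seeing the data were the comparison of excitatory neurons with reps 5-7, the tests of single target genes, the 3' UTR share among CDS and UTR peaks, the Cdr1 interval, gene list shares between the 2 forebrain lists, the alternatives of gene list shares against reps 1-4, and the alternatives that leave out rRNA peaks, keep CDS and UTR peaks alone or match random lists on CDS and UTR peaks. Ribosomal RNA peaks were those annotated as rRNA or mitochondrial rRNA and those on the strand of Gm42418 within 5000 bases of it. The other alternatives were peaks at or above the median score, the larger list reduced to its highest-scoring peaks until equal in number, protein-coding annotations alone, peaks overlapping an IgG peak left out, summed scores, 3' UTR peaks alone, miRNAs of 1 seed merged, stricter or looser overlaps, at least 2 peaks per gene and unmatched random lists.

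Genes and small RNAs were named by a rule fixed in advance. It takes, per list, the 10 small RNAs and the 10 target genes with the most peaks and the 5 peaks with the highest score (all IgG peaks). Per test it takes up to 10 small RNAs with the largest odds ratios in each direction, past the threshold and with at least 10 observed or expected peaks in the smaller list. It adds the 4 members with the most excitatory peaks per gene list, known pairs with an excitatory or IgG peak and the 10 known pairs with the most forebrain peaks. Single target genes tested and top peaks outside rRNA were named after their values were seen. Some results that the rule would name are not reported here.

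Gene symbols were matched to a RefSeq table of the GRCm38.p6 assembly. Of 11352 reps 1-4 symbols, 10294 matched as symbols, 392 as synonyms and 666 not at all; the numbers were 1390, 40 and 35 of 1465 for reps 5-7, 434, 18 and 9 of 461 for excitatory neurons and 2, 1 and 0 of 3 for IgG. Matches to the seed of each small RNA within its peaks were planned and not run, because they need a genome sequence that was not used here. Reads were not analysed here.

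The methods were tested on simulated data. In 20 simulations with small RNAs changed 3 times, 97.5% of raised and 57.5% of lowered small RNAs were called in lists sized like excitatory neurons and reps 1-4, 97.5% and 77.5% for reps 5-7 and reps 1-4, and 92.5% and 72.5% for excitatory neurons and reps 5-7. Only small RNAs expected to hold at least 10 peaks in the smaller list were changed, so recovery of rarer ones was not tested. False calls were 0.0570%, 0.0378% and 0.339%. Simulated peaks were drawn independently, whereas real peaks stack at shared places, so these rates do not carry over to the real lists. With 0, 50 and 100% of names kept in simulated overlapping peaks, 21.1%, 60.4% and 100% were counted as shared, against about 21.4% after shuffling. Of 100 simulated gene lists without and 100 with 8 added hit genes, 0 and 100 lay outside the matched range. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.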

Results

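Small RNAs loaded in Argonaute 2 (Ago2) were mapped together with the RNAs they bind in adult mouse forebrain. In this form of Ago cross-linking and immunoprecipitation, the small RNA and its target are ligated inside the Ago complex, so that 1 chimeric read names both partners. The 12 libraries fall into 3 kinds of precipitation. Anti-Ago2 was used for whole forebrain (7 libraries), anti-myc for forebrain carrying a tagged Ago2 induced in excitatory neurons through Camk2a-CreERT2 and tamoxifen (3 libraries), and a control immunoglobulin G (IgG) for background (2 libraries). Peaks of chimeric reads were called over pooled libraries, giving 4 lists: anti-Ago2 replicates 1 to 4 (reps 1-4), anti-Ago2 replicates 5 to 7 (reps 5-7), excitatory neurons and IgG. A list is a single pooled observation, so no value has a spread between replicates. All positions are on mm10.

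The reps 1-4 list held 246180 peaks of 746 small RNAs on 11352 genes, the reps 5-7 list 3611 peaks of 175 small RNAs on 1465 genes, and the excitatory list 766 peaks of 64 small RNAs on 461 genes. IgG gave 10 peaks of 8 small RNAs on 3 genes. The median peak score, a value of the authors, was 4 in the first 3 lists and 5.5 in the IgG list, and the lowest score was 3 in each of the 4 lists. Many peaks stacked at shared places: merging overlapping peaks of any small RNA left 183883 sites in reps 1-4, 2586 in reps 5-7, 651 in excitatory neurons and 5 in IgG.

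The IgG peaks lay almost entirely on ribosomal RNA. Of the 10, 6 joined let-7 family members to the mitochondrial 12S rRNA gene mt-Rnr1 between positions 640 and 659 of chromosome M. The highest scored 21 (let-7c-5p), followed by let-7a-5p at 11, let-7b-5p at 9, let-7d-5p at 7, let-7e-5p at 6 and let-7g-5p at 3. The other IgG peaks were miR-124-3p on the 16S rRNA gene mt-Rnr2 (M, 1868 to 1885, score 4), miR-124-3p (17, 39847466 to 39847485, score 4) and miR-9-5p (17, 39847511 to 39847519, score 4) on Gm42418, and miR-124-3p in an intergenic stretch of chromosome 16 (17222389 to 17222421, score 5). RefSeq lists Gm42418 as Rn18s-rs5, an 18S rRNA related sequence.

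The highest scores of the Ago2 and myc lists also lay on rRNA. The top let-7c-5p peaks of reps 5-7 (M, 645 to 646) and excitatory neurons (M, 644 to 646) did not overlap the IgG peak of let-7c-5p (M, 653 to 658). They did lie within IgG peaks of other let-7 members, among them let-7a-5p (M, 641 to 658) and let-7g-5p (M, 640 to 659). The 5 top-scoring peaks of reps 1-4 were let-7c-5p (score 30905), let-7a-5p (18449 and 18398) and let-7e-5p (10397) on mt-Rnr1 and miR-124-3p on mt-Rnr2 (12654). In reps 5-7 they were let-7c-5p (1296), let-7a-5p (919), let-7e-5p (594) and let-7b-5p (457) on mt-Rnr1 and miR-124-3p on mt-Rnr2 (450), level with miR-9-5p on Gm42418 (450). In excitatory neurons all 5 were let-7 peaks on mt-Rnr1: let-7c-5p (1124), let-7a-5p (833), let-7e-5p (611), let-7b-5p (386) and let-7d-5p (237). Ribosomal RNA took 2.06% of the peaks and 24.0% of the summed score in reps 1-4, 19.9% and 54.4% in reps 5-7, and 11.6% and 56.8% in excitatory neurons. Peaks that overlapped an IgG peak were 0.286%, 4.21% and 3.52% of the peaks of the 3 lists and held 7.60%, 24.9% and 49.9% of the summed score.

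miR-124-3p, a brain-enriched miRNA, had the most peaks in each of the 3 lists: 72138 in reps 1-4, 1017 in reps 5-7 and 287 in excitatory neurons. The next 9 in reps 1-4 were miR-9-5p, miR-26a-5p, miR-128-3p, miR-125b-5p, miR-29a-3p, miR-29b-3p, let-7c-5p, miR-9-3p and let-7a-5p. The reps 5-7 ranking had miR-127-3p in place of miR-9-3p, and the excitatory ranking had miR-138-5p, miR-127-3p and miR-7a-5p in place of miR-125b-5p, miR-9-3p and let-7a-5p.

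Counted over all regions, the target genes with the most peaks differed in kind between the lists. In reps 1-4, the top 10 included long neuronal genes hit almost entirely in introns: the potassium channel partner Kcnip4 (3045 peaks, 99.8% intronic), the protocadherin Pcdh9 (2350), the neuregulin Nrg3 (2102), the splicing factor Celf2 (1954), the neurexin Nrxn3 (1760), the receptor phosphatase Ptprd (1697), the postsynaptic scaffold Dlg2 (1675) and the adhesion protein Lsamp (1428). Gm42418 (1613) was also among them. In reps 5-7 the top 3 were Gm42418 (257 peaks), mt-Rnr1 (185) and mt-Rnr2 (149). They were followed by the astrocytic glutamate transporter Slc1a2 (27), the long noncoding RNAs 1700020I14Rik (25) and Malat1 (25), the synaptic kinase subunit Camk2a (24), the spectrin Sptbn1 (18), the dendritic microtubule protein Map2 (17) and Sparcl1 (17). In excitatory neurons Gm42418 (31), mt-Rnr1 (20) and mt-Rnr2 (11) stood beside Camk2a (14), Map2 (11), the postsynaptic density protein Ddn (7), Panx3 (6, all intronic), Sptbn1 (6), Agap2 (5) and the calcium pump Atp2b2 (5), the last 2 level with Ttyh1 among others. Within CDS and UTR peaks alone, Camk2a, Sptbn1 and Map2 were among the 10 leading genes of each list, and Slc1a2 led both anti-Ago2 lists.

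Both anti-Ago2 lists come from the same tissue and antibody, so their comparison shows how far 2 such lists differ. It is not a clean baseline. The lists share 0 library numbers, and whether their mice carried the tag is not stated, so batch or genotype may differ too. At least 2 libraries per peak were asked of 4 libraries in reps 1-4 and of 3 in reps 5-7. The lists differed most in introns, which held 47.6% of reps 1-4 peaks (95% Wilson interval 47.4 to 47.8) and 6.04% of reps 5-7 peaks (5.31 to 6.86). The reps 5-7 list was richer in 3' UTRs, at 33.6% (32.1 to 35.1) against 18.7% (18.5 to 18.8), and in coding sequence (CDS), at 31.2% (29.7 to 32.8) against 22.6% (22.4 to 22.8). Mitochondrial rRNA took 9.25% of reps 5-7 peaks against 1.02%, and lincRNA, the class that holds Gm42418, 8.64% against 2.00%.

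Of 24 regions tested between the anti-Ago2 lists, 11 passed an adjusted p of 0.05, 8 higher and 3 lower in reps 5-7 (Fisher's exact test, two-sided, Benjamini-Hochberg). The adjusted p was 4.68e-98 for 3' UTRs and 1.35e-31 for CDS. At or above the median score the CDS difference missed the threshold. The intron difference turned around when reps 1-4 was reduced to its 3611 highest-scoring peaks, where introns held 3.49%. With scores summed in place of peaks counted, the CDS difference was -5.64 points.

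**Figure D1:**
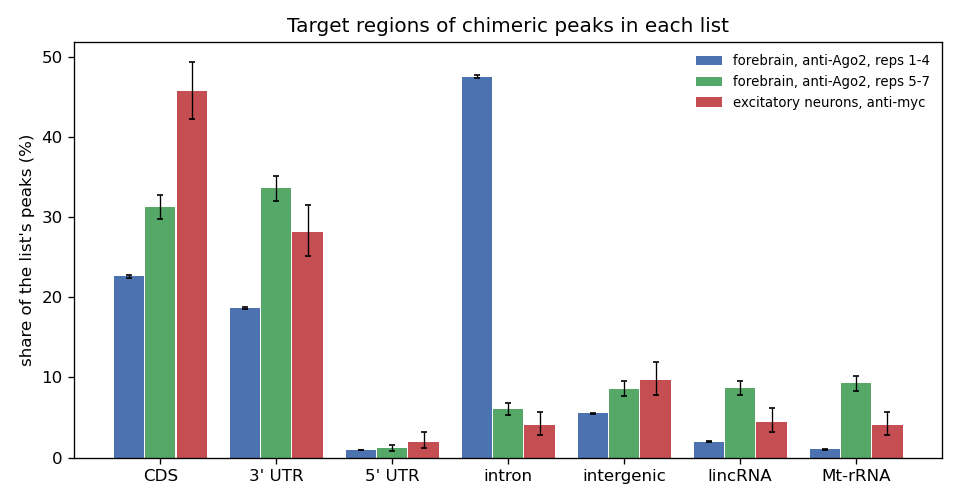
Share of each list's peaks (vertical axis, percent) in 7 target regions (horizontal axis) for reps 1-4, reps 5-7 and excitatory neurons, with Wilson 95% intervals as error bars. Introns hold 47.6% of the reps 1-4 peaks and 6.04% and 4.05% of the other 2 lists, and CDS is highest in excitatory neurons at 45.8%.

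Small RNA usage differed less between the anti-Ago2 lists than region usage. miR-7a-5p, a miRNA with many known sites in Cdr1as, the circular RNA antisense to Cdr1, took 0.554% of reps 5-7 peaks (20 peaks) and 0.130% of reps 1-4 peaks, an odds ratio of 4.27 (adjusted p 1.71e-05). Of the 29 miR-7a-5p and miR-7b-5p peaks of reps 5-7, 21 lay in the Cdr1 interval (below), and the test counts such neighbouring peaks as independent. miR-29a-3p (odds ratio 1.54, adjusted p 8.57e-06), let-7c-5p (1.45, 0.00641) and miR-29b-3p (1.38, 0.00640) were also higher in reps 5-7. miR-101a-3p (0.343, 0.0155), miR-9-3p (0.541, 0.00382) and miR-125b-5p (0.595, 8.57e-06) were lower. In all, 8 small RNAs passed the threshold, 5 higher and 3 lower, and the remaining one, named after its value was seen, was miR-7b-5p (odds ratio 6.03). None passed when reps 1-4 was reduced to its 3611 highest-scoring peaks, where the miR-7a-5p difference was -0.775 points. In 3' UTRs alone the miR-7a-5p and let-7c-5p differences also turned, to -0.111 and -0.878 points.

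Among fixed miRNA lists, the neuron enriched list took 51.6% of reps 5-7 peaks and 54.2% of reps 1-4 peaks (adjusted p 0.0125), and the let-7 family 10.1% and 8.81% (0.0214). The oligodendrocyte, astrocyte, microglia and vascular miRNA lists gave adjusted p of 0.521 to 0.539. Counted by peaks on fixed gene lists, astrocyte genes were higher in reps 5-7, at 1.69% against 0.678% (adjusted p 3.84e-09), and postsynaptic genes lower, at 0.969% against 2.48% (6.12e-10). Excitatory neuron genes (0.803% against 0.485%, 0.0365) and oligodendrocyte genes (0.554% against 0.314%, 0.0413) were higher, presynaptic genes (1.80% against 2.38%, 0.0413) were lower, and the other 5 lists did not pass. The presynaptic call was lost under 4 of 6 settings and in CDS and UTR peaks alone turned to 0.864 points higher, past the threshold; there the postsynaptic difference turned to 0.204, not past it, and the excitatory neuron and oligodendrocyte calls were lost, the former also at or above the median score. With reps 1-4 reduced to its 3611 highest-scoring peaks no list passed, and with rRNA left out or protein-coding peaks alone miRNA pathway and activity-regulated genes passed as well, higher in reps 5-7.

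Most reps 5-7 peaks recurred in the reps 1-4 list. Of the 3611, 3160 (87.5%, 86.4 to 88.5) overlapped a reps 1-4 peak of the same small RNA by at least 1 base on the same strand, and 95.2% overlapped a peak of any small RNA. Shuffling small RNA names among the reps 5-7 peaks gave a mean of 35.5% and at most 37.2% in 1000 shuffles (permutation p 0.000999, the smallest these shuffles can give). Asking for a reciprocal overlap of 50% left 45.3%, against 11.8% shuffled.

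The excitatory list was set against reps 1-4 to ask which interactions tagged Ago2 in excitatory neurons recovers out of those of the whole forebrain. It differs from both anti-Ago2 lists in antibody and in the tagged protein as well as in cell type. These cannot be told apart in any comparison of the excitatory list below. Coding sequence was the leading target region of the excitatory list, with 351 of 766 peaks (45.8%, 42.3 to 49.4) against 22.6% of reps 1-4. The 3' UTR share was 28.2% (25.1 to 31.5) against 18.7%, and the intron share 4.05% (2.87 to 5.69) against 47.6%. Intergenic positions held 9.66% against 5.52%, mitochondrial rRNA 4.05% against 1.02%, lincRNA 4.44% against 2.00% and 5' UTRs 1.96% against 0.956%.

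Of 24 regions, 9 passed, 8 higher and only introns lower in the excitatory list. Adjusted p were 3.69e-44 for CDS, 1.24e-09 for 3' UTRs, 8.94e-160 for introns and 2.49e-05 for intergenic positions. At or above the median score the 3' UTR difference missed the threshold. Against the 766 highest-scoring peaks of reps 1-4, introns were higher in the excitatory list by 2.48 points. With summed scores the CDS share was lower, by -2.06 points, and the 3' UTR share by -6.30 points.

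Several miRNAs took larger shares in the excitatory list than in reps 1-4, though miR-29a-3p, miR-29b-3p and miR-7a-5p were also higher in reps 5-7 than in reps 1-4. miR-124-3p reached 37.5% of peaks (34.1 to 40.9) against 29.3% (adjusted p 9.35e-05), miR-29a-3p 7.57% against 3.63% (2.67e-05), miR-29b-3p 6.27% against 3.22% (8.96e-04), miR-127-3p 2.61% against 1.10% (0.0191) and miR-7a-5p 1.70% against 0.130% (1.93e-08, odds ratio 13.2). Of the 17 excitatory peaks of miR-7a-5p and miR-7b-5p, 12 lay in the Cdr1 interval (below). The miR-7a-5p test counts such neighbouring peaks of 1 locus as independent. miR-9-3p had no excitatory peak, which allows up to 0.392% of 766 peaks, against 1.83% of reps 1-4 (9.88e-05). miR-125b-5p was lower at 0.783% against 4.43% (7.42e-07, odds ratio 0.170), as were miR-26a-5p at 4.05% against 6.90% (0.0298) and miR-9-5p at 6.79% against 10.7% (0.0102). Both miR-9-3p and miR-125b-5p were also lower in reps 5-7 than in reps 1-4.

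In all, 11 of 264 small RNAs passed, 6 higher and 5 lower. The other 2, named after their values were seen, were miR-7b-5p (4 peaks, higher) and miR-153-3p (0 peaks, lower). Reduced to peaks at or above the median score of each list, 2 passed, miR-7a-5p and miR-124-3p. With reps 1-4 reduced to its 766 highest-scoring peaks, 5 passed, and the miR-7a-5p difference was -0.392 points; miR-7a-5p also did not pass with 3' UTR, CDS and UTR or protein-coding peaks alone.

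**Figure D2:**
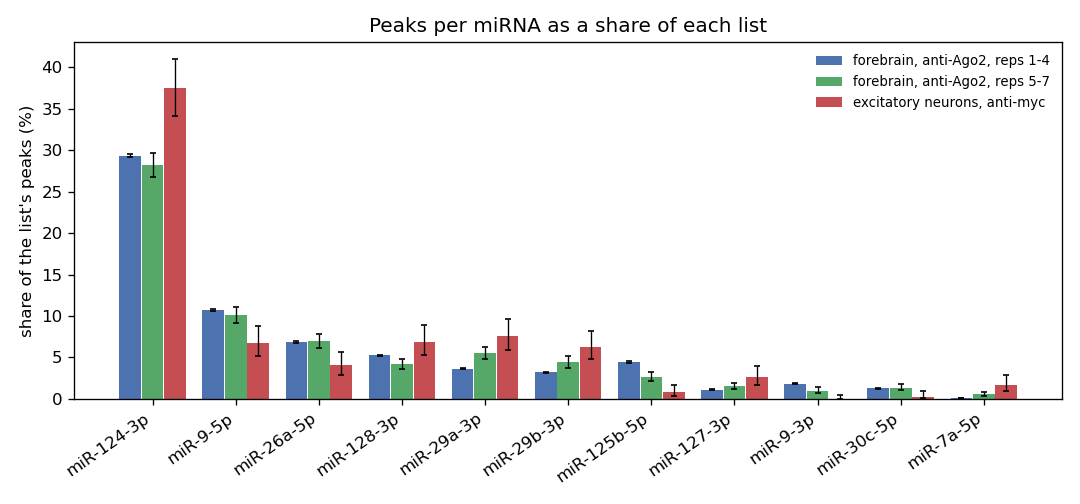
Share of each list's peaks (vertical axis, percent) held by 11 miRNAs (horizontal axis) in reps 1-4, reps 5-7 and excitatory neurons, with Wilson 95% intervals as error bars. miR-124-3p holds 29.3%, 28.2% and 37.5%, while miR-125b-5p holds 4.43%, 2.69% and 0.783%.

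Neuron enriched miRNAs as a fixed list took 61.4% of excitatory peaks (57.9 to 64.7) and 54.2% of reps 1-4 peaks (adjusted p 4.43e-04). The difference was 7.12 points, and that of the list member miR-124-3p alone was 8.16 points, so the other members as a group were not higher. The vascular list, led by miR-126a-3p, had 0 of 766 excitatory peaks against 1.03% in reps 1-4 (0.00252). The oligodendrocyte (miR-219 and miR-338), astrocyte (miR-21a, miR-204, miR-143) and microglia lists also had 0 excitatory peaks, against 0.317%, 0.395% and 0.170% in reps 1-4. Adjusted p for these were 0.223, 0.165 and 0.645, so a difference was not detectable at this depth. In reps 1-4, miR-143-3p alone held 458 of the 973 peaks of the astrocyte list. Whether it marks astrocytes was not tested, so this share may not stand for astrocytes. The let-7 family took 10.2% against 8.81% (0.223). The neuron enriched and vascular calls were lost against the 766 highest-scoring peaks of reps 1-4. Fewer miRNA lists passed at or above the median score as well.

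Nearly all excitatory peaks were found again in the forebrain list. Of the 766, 713 (93.1%, 91.1 to 94.7) overlapped a reps 1-4 peak of the same small RNA, against a mean of 39.5% and at most 43.0% after shuffling names (permutation p 0.000999, the smallest possible). Any small RNA counted, 96.7% overlapped, and a reciprocal overlap of 50% left 56.5% against 18.3% shuffled.

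The excitatory list was also set against reps 5-7, a comparison chosen after seeing the data because the calling summaries give both sets of libraries the same 3 library numbers and their lists are closer in size. CDS was again higher in the excitatory list, at 45.8% against 31.2% (adjusted p 3.12e-13). The 3' UTR share was lower, at 28.2% against 33.6% (0.0107), as were mitochondrial rRNA, at 4.05% against 9.25% (3.03e-06), and lincRNA, at 4.44% against 8.64% (1.66e-04). Introns held 4.05% and 6.04% (0.0694), and passed as lower in excitatory neurons with protein-coding annotations alone or with rRNA left out. The remaining 6 of 11 regions did not pass. The 3' UTR difference turned to 6.53 points higher against the 766 highest-scoring peaks of reps 5-7 and missed the threshold at or above the median score. The CDS difference stayed past it in each setting that was tested.

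Among CDS and UTR peaks alone, 3' UTRs held 216 of 582 excitatory peaks (37.1%, 33.3 to 41.1) and 1213 of 2383 reps 5-7 peaks (50.9%, 48.9 to 52.9; Fisher's exact p 2.17e-09), and 44.2% in reps 1-4. miR-124-3p and miR-128-3p, tested singly after the values of the individual miRNAs were seen, had 38.4% against 53.1% (Fisher's exact p 7.29e-05) and 17.0% against 47.6% (2.90e-04) in 3' UTRs. Others went the other way, untested, among them let-7c-5p (36.8% against 24.7%), let-7a-5p (44.4% against 33.3%) and miR-29b-3p (51.3% against 45.9%). This share was examined after the region results were seen.

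miR-124-3p was also higher than in reps 5-7, at 37.5% of peaks against 28.2% (26.7 to 29.7; adjusted p 2.42e-05, odds ratio 1.53). miR-128-3p took 6.92% against 4.15% (0.0161) and miR-7a-5p 1.70% against 0.554% (0.0217). Lower were miR-30c-5p, at 0.261% against 1.36% (0.0365), miR-125b-5p, at 0.783% against 2.69% (0.0161), miR-26a-5p, at 4.05% against 6.92% (0.0166), and miR-9-5p, at 6.79% against 10.1% (0.0217). These 7 were among 10 that passed of 45 tested, with miR-9-3p (0 peaks) and, named after their values were seen, miR-153-3p (0 peaks) and miR-29c-3p (1 peak) also lower. Of small RNAs, 2 passed at or above the median score, 2 against the 766 highest-scoring peaks and 0 in 3' UTRs, where the miR-128-3p difference turned to -0.418 points. The miR-7a-5p difference turned to -0.131 points against the 766 highest-scoring peaks, and miR-124-3p did not pass there. Most miR-7 peaks of both lists lay at the Cdr1 interval (below) and are counted as independent by the test. miR-29a-3p, miR-29b-3p and miR-127-3p, higher than in reps 1-4, did not pass against reps 5-7 (Fisher's exact test, adjusted p 0.0956, 0.0997 and 0.129).

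Neuron enriched miRNAs took 61.4% against 51.6% (adjusted p 5.50e-06), and this stayed past the threshold in each setting run. Nearly all of this difference of 9.71 points came from the list member miR-124-3p, which alone differed by 9.30 points. The other members as a group were not shown to differ. Vascular miRNAs had 0 of 766 peaks against 0.886% (0.0114), a call that was lost under 4 of the 6 settings. The astrocyte list had 0 peaks against 0.498% (0.115), the oligodendrocyte list 0 against 0.415% (0.134) and the microglia list 0 against 0.111% (1); let-7 was at 10.2% and 10.1% (1). Of the excitatory peaks, 425 (55.5%, 51.9 to 59.0) overlapped a reps 5-7 peak of the same small RNA, against 19.3% after shuffling names (permutation p 0.000999, the smallest possible), and 64.6% overlapped any peak.

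Genes of astrocytes were missing from the excitatory targets. All 20 astrocyte marker genes had reps 1-4 peaks and 12 had reps 5-7 peaks, led by the glutamate transporter Slc1a2 (27 peaks), glutamine synthetase Glul (8) and the glycolytic enzyme Aldoc (7), but none had an excitatory peak. As a share of peaks this was 0 of 766, which allows up to 0.392%, against 61 of 3611 (1.69%, 1.32 to 2.16; adjusted p 1.08e-04), and against 0.678% of reps 1-4 (0.0409, a call lost under 4 of 6 settings). Peaks of 1 gene are not independent, and Slc1a2 alone held 27 of the 61. Counted by target genes, 0 of 461 against 12 of 1465 in reps 5-7, the difference was not past the threshold (Fisher's exact p 0.0814). Of the excitatory neuron markers, 1 of the 18 targeted in forebrain had excitatory peaks: Camk2a, with 14. Peaks on this list made 1.83% against 0.803% in reps 5-7 (0.0478, a call lost under 5 of 6 settings) and 0.485% in reps 1-4 (1.72e-04, lost against the 766 highest-scoring peaks).

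The other cell types gave few peaks. None of the 16 targeted inhibitory neuron markers had an excitatory peak, against 4 peaks in reps 5-7 on Gad1 and Gad2 (adjusted p 1), and none of the 19 vascular markers had one (1). The oligodendrocyte list had 4 excitatory peaks (0.522% against 0.554% in reps 5-7, adjusted p 1). The microglia list had 1 (0.877).

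The presynaptic list had 8 of 20 genes with an excitatory peak, above the central 95% (1 to 7) of 10000 random gene lists matched on reps 1-4 peak number, with Syp and Unc13a at 3 peaks each, Bsn at 2 and the other 5 genes, among them Cplx1, at 1. The activity-regulated list had 5 of 17, above the matched range of 0 to 4: Arc (4 peaks), Egr1 (3), Crebbp (1), Nptx2 (1) and Nr4a1 (1), the last named after its values were seen. Postsynaptic and glutamate receptor genes had 7 of 24 (range 1 to 8), with Arc (4), Gria3 (2), Gria4 (2) and Grm5 (2), and the miRNA pathway 3 of 19 (0 to 5), with Tnrc6b (2), Ago1 (1) and Ddx6 (1). Excitatory neuron, inhibitory neuron, oligodendrocyte, microglia and vascular lists also lay within their ranges, and so did astrocyte genes with 0 of 20, a count that 4.85% of matched lists reached. The ranges of all these lists began at 0, so no count could lie below them and a lack of targets could not be detected this way.

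By share of peaks, activity-regulated genes stood at 1.31% in excitatory neurons, 0.388% in reps 5-7 (adjusted p 0.0235, a call lost under 3 of 6 settings) and 0.246% in reps 1-4 (1.72e-04, lost against the 766 highest-scoring peaks). The presynaptic share was 1.70%, 1.80% (1) and 2.38% (0.428), the postsynaptic share 1.70%, 0.969% (0.214) and 2.48% (0.428), and the miRNA pathway share 0.522%, 0.471% (1) and 0.308% (0.428). In CDS and UTR peaks alone the presynaptic and postsynaptic differences from reps 1-4 turned to 0.614 and 1.01 points higher, neither past the threshold. The presynaptic and activity-regulated positions fell within range when genes needed at least 2 excitatory peaks, when random lists were matched on CDS and UTR peaks, and with reps 1-4 reduced to 766 peaks. In the last 2 of these settings the astrocyte list lay below the range, and its share of peaks stayed lower than in reps 5-7 in each setting run.

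**Figure D3:**
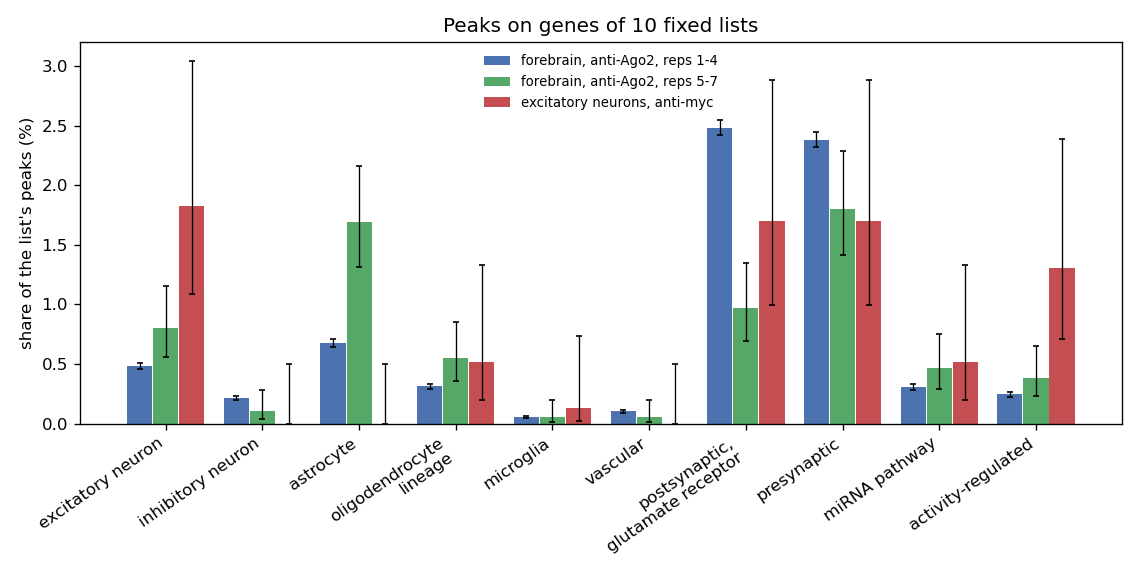
Share of each list's peaks (vertical axis, percent) on the genes of 10 fixed lists (horizontal axis) in reps 1-4, reps 5-7 and excitatory neurons, with Wilson 95% intervals as error bars. Astrocyte genes hold 0.678%, 1.69% and 0, and excitatory neuron genes 0.485%, 0.803% and 1.83%.

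Single target genes were compared after the data were seen. Within CDS and UTR peaks, Ddn (7 excitatory peaks, odds ratio 15.8, adjusted p 0.00155), Map2 (11, 7.08, 0.00155), Camk2a (13, 5.10, 0.00387) and the synaptic immediate early gene Arc (4, 22.5, 0.0377) were higher in excitatory neurons than in reps 1-4, of 3099 genes tested. Against reps 5-7, over all peaks with a gene and not CDS and UTR peaks alone, Ddn, Camk2a and Map2 were higher (adjusted p 0.0238, 0.0243 and 0.0258). There mt-Rnr2, Gm42418, mt-Rnr1 and Slc1a2 were lower (0.00510, 0.0238, 0.0238 and 0.0422), of 32 tested. No gene passed against reps 5-7 with rRNA peaks left out or with CDS and UTR peaks alone, and 1 passed against reps 1-4 at or above the median score. With the CDS and UTR peaks of reps 1-4 reduced to their 582 highest scores, the Camk2a difference turned to -0.172 points and that of Map2 was 0.

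Outside rRNA, the excitatory peaks with the highest scores were miR-668-3p at its own hairpin gene Mir668 (12, 109734736 to 109734752, score 106), miR-125a-5p in the intergenic stretch on chromosome 16 where IgG also had a peak (17222391 to 17222406, score 68), miR-124-3p in the CDS of Camk2a (18, 60958578 to 60958591, score 55), miR-124-3p in an intron of Panx3 (9, 37663676 to 37663692, score 46) and miR-128-3p in the CDS of the ankyrin Ank2 (3, 127010964 to 127010981, score 25). The Camk2a site also carried the highest miR-124-3p score on that gene in reps 1-4 (830, at 60958586 to 60958590) and in reps 5-7 (39, at 60958577 to 60958591). In the anti-Ago2 lists the highest scores outside rRNA included miR-124-3p in the 3' UTR of the protocadherin Pcdh1 (18, 38189786, score 3591 in reps 1-4 and 76 in reps 5-7), miR-26a-5p in an intergenic stretch of chromosome 3 (5860631 to 5860636, score 5596 in reps 1-4), miR-124-3p in the 3' UTR of the lysosomal sulfatase gene Ids (X, 70344137, score 90 in reps 5-7) and miR-9-5p in the CDS of Sparcl1 (5, 104087067 to 104087073, score 89 in reps 5-7).

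Of 59 textbook miRNA and target pairs fixed in advance, 34 had a peak in reps 1-4, 5 in reps 5-7, 1 in excitatory neurons and 0 in IgG. In 3' UTRs alone the numbers were 29, 5, 1 and 0. Pairs were matched by annotated gene symbol, so miR-7a-5p with Cdr1 or Cdr1os and miR-671-5p with Cdr1os counted as absent. Peaks of miR-7a-5p in the Ago2 and myc lists and of miR-671-5p in reps 1-4 did lie at the Cdr1 locus (below). They were not assigned to a gene, so the counts of pairs may be too low. The pair counted in excitatory neurons was miR-29b-3p with Nrep, in its 3' UTR (18, 33438142 to 33438166, minus strand, score 4). It overlapped the peak of this pair in reps 1-4 (33438145 to 33438156, score 122) and in reps 5-7 (33438140 to 33438162, score 9). Pairs with many reps 1-4 peaks included miR-125b-5p with the NMDA receptor subunit Grin2a (20 peaks, 16 of them intronic), let-7 with Igf1r (19) and Dicer1 (16), miR-124-3p with Itgb1 (10), Cd164 (8) and Lamc1 (6), miR-26a-5p with Gsk3b (8), miR-29a-3p with Dnmt3a (7) and miR-9-5p with Onecut2 (7). Itgb1 and Cd164 had 2 peaks each in reps 5-7, and Lamc1 and Dnmt3a 1 each.

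miR-7 peaks gathered on a short stretch of chromosome X, the RefSeq interval of Cdr1 (61183246 to 61185558), on the plus strand. This interval was examined after the data were seen. It held 21 of the 29 miR-7a-5p and miR-7b-5p peaks of reps 5-7 and 12 of the 17 of excitatory neurons, and 87 of the 423 of reps 1-4. By summed score the interval took 83.0%, 79.2% and 75.7% of all miR-7 signal of reps 5-7, excitatory neurons and reps 1-4. Other small RNAs with a peak on it numbered 46 in reps 1-4, 6 in reps 5-7 and 2 in excitatory neurons. IgG had no peak there. The cluster went on past the end of the interval: with 2000 bases added on each side it held 22 of 29, 14 of 17 and 107 of 423 miR-7 peaks, and 84.6%, 88.5% and 82.7% of the signal. The reference table gives no strand and has no Cdr1as entry at these positions, so the peaks were not assigned to Cdr1 or to its antisense RNA.

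**Figure D4:**
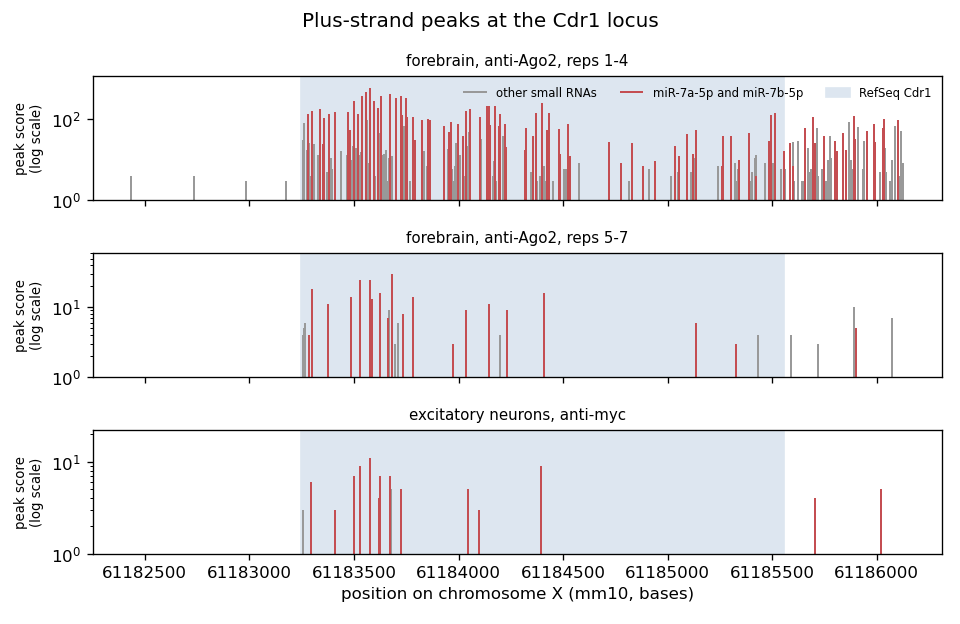
Peaks on the plus strand around the RefSeq interval of Cdr1 (shaded) on chromosome X, with position on the horizontal axis (mm10, bases) and the authors' peak score on the vertical axis (log scale), for reps 1-4, reps 5-7 and excitatory neurons. Lines for miR-7a-5p and miR-7b-5p are red and lines for other small RNAs grey, and 12 of the 14 excitatory peaks inside the interval belong to miR-7.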

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

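The tests in this part were chosen after the results were seen, apart from the gene mix test of the 3' UTR share, whose prediction was written before its value.

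Fragments of transfer RNA (tRFs) appear among the small RNAs, and no comparison above examines them as a class; 3 single tRFs were among the small RNAs tested against reps 1-4 and did not pass (adjusted p 1). Forebrain reps 1-4 held 143 tRF peaks, reps 5-7 held 3, and excitatory neurons and IgG held 0. They were singled out because peaks are present where IgG has none. As shares, 0.0581% and 0.0831%, they do not lie above the 30% that 0 of 10 IgG peaks allows. The 143 peaks came from 33 different tRFs, led by tRF-5011b (45 peaks), tRF-1006 (21) and tRF-5012b (16), and 40 of them lay on rRNA, 67 in introns and 20 in CDS or UTRs. Their highest score was 61.

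Introns held 47.6% of the peaks of reps 1-4 and 6.04% of those of reps 5-7. A larger share of low scores does not account for it as the scores stand, since 40.3% and 38.1% of their peaks had the lowest score. Weighting reps 1-4 to the score mix of reps 5-7 could therefore change little, and gave 46.9% (46.8 to 47.1). At score 4 the intron shares were 53.0% and 4.49%. Scores are not scaled to library size, so 1 score need not mean the same in both lists. By rank, the 3611 highest-scoring reps 1-4 peaks had 3.49% in introns (2.94 to 4.14), so a longer list that reaches further down a ranking of sites could still explain it, but score and rank disagree and the depth of each list is not known. A difference between library batches also stays open, because the lists share 0 library numbers. The 2 lists come from 1 tissue and 1 antibody, but whether their mice carried the tag is not stated. No biological explanation was tested.

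Astrocyte genes had 0 of 766 excitatory peaks and 61 of 3611 reps 5-7 peaks. Chance in a short list stays open: merged sites gave 0 of 613 against 52 of 2456 (Fisher's exact p 1.24e-05, and 0.00139 without Slc1a2), but sites of 1 gene are not independent, and counted by genes the p was 0.0814. The smaller 3' UTR share does not account for it: reps 5-7 weighted to the excitatory mix of regions still had 1.84% (0.559 to 3.80 over resampled genes), above the 0.499% that 0 of 766 allows by its Wilson bound, though narrowly at the lower end. A restriction of tagged Ago2 to excitatory neurons may explain it as a hypothesis, but predicts fewer oligodendrocyte peaks too, and that share was 0.522% with 4 peaks, too few to tell. RNA from other cells in either precipitate was not tested. Antibody and tagged protein also differ between these lists and cannot be told apart from cell type.

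Among CDS and UTR peaks, 3' UTRs held 37.1% in excitatory neurons and 50.9% in reps 5-7. The mix of small RNAs does not account for it: reps 5-7 weighted to the excitatory mix still gave 48.9% (46.6 to 51.1). Nor does a restriction to high scores, since the highest-scoring reps 5-7 peaks gave 53.6% (49.5 to 57.6). The mix of target genes could account for part of it: on genes in both lists, reps 5-7 weighted to the excitatory mix gave 42.6% (39.6 to 45.3) against 37.6% (33.4 to 42.0). By the rule as first written 42.6% lies above the bound of 42.0% and would exclude gene mix, but the interval of the weighted value was added after this near miss was seen, and with it the question stays open.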

How the results depend on the processing

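No paired analysis was possible because the lists are pooled and hold no values per library, and leave-one-out was not possible for the same reason. The planned seed-match test was not run, because no genome sequence was given. The short excitatory list limits what can be detected, and the alternatives that leave out rRNA, keep CDS and UTR peaks alone or match on them, the alternatives of gene list shares against reps 1-4, and the whole comparison with reps 5-7, were chosen after seeing the data. Single regions were counted among the values that answer a comparison. Of these values, 107 stayed the same, 49 moved, 3 fell below the threshold, 2 passed it newly and 8 reversed. Of the other values, among them single genes and miRNAs, 333 stayed, 114 fell below the threshold, 7 passed newly and 39 reversed. Unless stated, the cause was not tested. Values in threes are for excitatory neurons against reps 1-4, reps 5-7 against reps 1-4 and excitatory neurons against reps 5-7, values in pairs, unless said otherwise, for excitatory neurons against reps 1-4 and against reps 5-7, and differences are in points.

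At or above the median score, 146970, 2236 and 430 peaks were left in reps 1-4, reps 5-7 and excitatory neurons. There the 3' UTR difference was 4.69 for excitatory neurons against reps 1-4 and -4.84 against reps 5-7, and the CDS difference between forebrain lists 1.76, all missing the threshold. The count of small RNAs was 2, 4 and 2 (from 11, 8 and 10), that of miRNA lists 1 and 1 for excitatory neurons against reps 1-4 and reps 5-7 (from 2 and 2), and that of target genes 1 and 1 (from 4 and 7), with fewer peaks tested. let-7 turned to -0.515 and -1.59, and against reps 5-7 the oligodendrocyte and presynaptic gene lists turned to 0.215 and 0.376.

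With the larger list reduced to its highest scores, introns turned to 2.48, 2.55 and 2.87, the 3' UTR to 6.53 against reps 5-7, and miR-7a-5p to -0.392, -0.775 and -0.131. Regions past the threshold between forebrain lists were 7 (from 11), small RNAs 5, 0 and 2, miRNA lists 0 against reps 1-4, gene lists outside the range of random lists 1 (from 2), gene list shares 0, 0 and 1 (from 3, 5 and 3), and target genes 1 and 3. let-7 turned to -0.131 and -1.70, the presynaptic and miRNA pathway gene lists to 0.653 and -0.261 against reps 5-7, and Camk2a to -0.172 against reps 1-4. Gene list shares of excitatory neurons against reps 1-4 turned to -0.131 (oligodendrocyte), 1.44 (postsynaptic) and 1.04 (presynaptic), and those of reps 5-7 against reps 1-4 to -0.471 (excitatory neuron), 0.0831 (inhibitory neuron), -0.194 (oligodendrocyte), -0.0277 (microglia), 0.111 (postsynaptic) and 0.498 (presynaptic).

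With protein-coding annotations alone, 4 and 4 regions passed for excitatory neurons and reps 5-7 against reps 1-4 (from 9 and 11, with fewer regions left), 6 and 5 small RNAs, and 1 miRNA list and 1 gene list share against reps 5-7; introns passed there with -3.46, and the miRNA pathway list turned to -0.0151. Between forebrain lists the presynaptic share was lost with protein-coding annotations alone, rRNA left out or IgG overlaps left out, at -0.0948, -0.185 and -0.508, and the miRNA pathway and activity-regulated shares passed newly in the first 2 of these. With rRNA left out, introns passed against reps 5-7 with -2.95, let-7 turned to -0.238 and -0.0714, and 1 miRNA list and 0 target genes passed against reps 5-7. With IgG overlaps left out, 0 IgG peaks remained by construction, and let-7 turned to -0.830 against reps 5-7.

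Summed scores, of which rRNA holds 24.0% to 56.8%, gave CDS -2.06, -5.64 and 3.59, 3' UTRs -6.30, -0.117 and -6.18, and introns -22.1, -21.7 and -0.444. In 3' UTRs alone 4 small RNAs passed against reps 1-4 and 0 against reps 5-7; miR-127-3p turned to -0.0187, miR-7a-5p and let-7c-5p between forebrain lists to -0.111 and -0.878, and miR-128-3p against reps 5-7 to -0.418. In CDS and UTRs alone 5 small RNAs passed against reps 1-4, and against reps 5-7 1 miRNA list, 1 gene list share and 0 target genes; let-7 turned to -4.15 against reps 1-4, miR-7a-5p between forebrain lists to -0.0738, and the miRNA pathway list against reps 5-7 to -0.0261. Gene list shares there turned, against reps 1-4, to -0.0731 (microglia), 1.01 (postsynaptic) and 0.614 (presynaptic) for excitatory neurons, and to 0.0178 (inhibitory neuron), -0.0731 (microglia), 0.204 (postsynaptic) and 0.864 (presynaptic) for reps 5-7, for which 2 shares passed (from 5). Seeds merged gave 5 small RNAs between forebrain lists. Over all regions 11 target genes passed against reps 1-4. Any small RNA counted, overlaps were 96.7%, 95.2% and 64.6%. At least 2 peaks per gene left 0 gene lists outside the range, and matching on CDS and UTR peaks 1.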

Other observations

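Values in this part were chosen after they were seen, and no explanation of them was tested.

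Some places carried peaks of a miRNA in all 3 lists from Ago2 or myc precipitation. miR-7a-5p lay in the 3' UTR of Ids on chromosome X in reps 1-4 (70344171 to 70344172, score 325), reps 5-7 (70344170 to 70344190, score 21) and excitatory neurons (70344168 to 70344188, score 5). miR-668-3p at Mir668, its own hairpin gene, scored 269, 34 and 106. In reps 1-4 miR-7a-5p also lay on the long noncoding RNA 1700020I14Rik, a RefSeq synonym of Oip5os1 (2, 119602146 to 119602162, score 37).

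Panx3 had 6 excitatory peaks of 6 small RNAs in an intron, 3 peaks in reps 5-7 and 0 in reps 1-4. Within CDS and UTRs, the genes with the most reps 1-4 peaks were Slc1a2 (511), Camk2a (464), Sptbn1 (327), Map2 (282) and Ank2 (280), of 103963 such peaks. Introns held 59.5% of the reps 1-4 peaks with the lowest score, 10.5% of those of reps 5-7 and 6.25% of those of excitatory neurons.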
